A study of Mus musculus with 22 samples.

How the data were processed

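The sample labels describe 22 libraries from mouse skin fibroblasts: chromatin immunoprecipitation with an antibody to SSRP1 (a subunit of the histone chaperone FACT) or to histone H3, an IgG control, and MNase-digested input DNA. Each library was assigned to a group by its title. The submitters' processing notes name CASAVA 1.8.2, BWA 0.7.15, Picard 1.97, deepTools and the mouse genome build mm10, without saying which step used each.

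The names of the libraries in the processed files were compared with the titles and descriptions of the 22 samples. None of the 26 columns of gene counts matched a sample, and none named an antibody or input. None of the 16 library names in the insert size table matched either. These columns and rows can belong to another series or to another kind of assay. Their values were therefore not used, and no normalization or test was run on them. The only settings varied were the rules for matching names. The comparisons planned before the data were examined (transformed against immortalized cells for SSRP1, for H3, for SSRP1 relative to H3 and for input, SSRP1 against H3, IgG or input, H3 against input, and insert sizes) were therefore not computed.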

Results

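The samples were libraries from mouse skin fibroblasts at 2 stages, immortalized cells and cells transformed further with an activated HRas. SSRP1 immunoprecipitation was represented by 4 libraries from immortalized cells and 5 from transformed cells. Histone H3 immunoprecipitation was represented by 3 libraries from immortalized cells and 5 from transformed cells. MNase-digested input DNA came from immortalized cells in 1 library and from transformed cells in 3 libraries. The IgG control was 1 library from transformed cells. By the number in its title (contradicted by other labels in 3 samples), each library came from culture variant 2 or 3. The library numbers should therefore not be read as numbers of independent cultures.

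The design implied a comparison of SSRP1 and H3 occupancy over genes between transformed and immortalized cells, with input DNA and IgG as background. Names matched one of these 22 libraries in 0 of the 26 count columns and 0 of the 16 insert size entries. It was also not established that those columns and entries hold occupancy values. For these reasons occupancy in the 22 libraries was not analysed here. No gene, gene group or region is therefore reported as higher or lower in either stage, and no difference between the stages was tested.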

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

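No paired analysis was possible because no count column or insert size entry matched, by name, one of the 22 libraries, and for the same reason no other normalization, filter or model was run. Looser rules for matching names were added after the files had been seen. By the culture code in the titles alone, 18 of the 42 column and row names shared a code with the samples. Names were counted per column or row, so a repeated library was counted each time. Each shared code belonged to at least 2 samples, from different antibodies or input. The titles of 3 samples disagree with their source name or characteristics on the culture variant. With the variant taken from the source name, each shared code belonged to at least 3 samples, and with the variant from the characteristics to at least 4. The number of names that matched a single sample was 0 under each of these rules. This 0 was fixed in advance by the sample labels, in which each shared code belonged to more than a single sample. The looser rules were therefore no independent check of the match against titles and descriptions.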
